A study of Aspergillus luchuensis with 9 samples.

How the data were processed

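RNA-seq was done on 9 libraries of Aspergillus luchuensis mut. kawachii, 3 each of a control, ΔhepA and ΔlaeA. Per the labels' protocols, total RNA was enriched for poly(A) RNA and made into stranded libraries. The authors deposited 1 table of FPKM values (fragments scaled by transcript length and by the library's mapped total) from RSEM, with 1 column per library. The submitters' processing notes name FastQC 0.11.9, Trim Galore 0.6.7, Trimmomatic 0.39, cutadapt 3.7, STAR 2.7.9a, featureCounts 2.0.1 and RSEM 1.3.1, with no role or order; the genome build is not given in the sources used here. All 12941 gene identifiers matched the reference table of gene names. Start and end equalled the reference in 12936, and the other 5 are listed on 2 segments. The table gave a symbol other than the locus tag for 2243.

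FPKM values are scaled by each library's own mapped total, so a few abundant transcripts can lower all other values of a library. FPKM sums ran from 1368965 to 1716065. The deposited FPKM values are not counts, so count tests were not used, and read totals were not used here. Genes measured by few fragments take values in steps, and the ratio of these steps between libraries gave the relative depth (600 to 1473 low genes per library, FPKM between 0.1 and 1.2). No 2 libraries held the same values: at most 1.65% of genes above 0 were equal between 2 of them. An exact 0 is described as listed at 0.

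Genes with at least 1 FPKM in at least 3 libraries were tested (10009; 2168 with a symbol). log2(FPKM + 1) was fitted by limma 3.58.1 in R 4.3.3 with group means over all 9 libraries (6 residual degrees of freedom) and eBayes with a mean trend. Differences are on that scale, which understates changes of low genes. P-values are two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Data of 10009 genes were simulated with the real spread per gene and independent libraries. Changes were planted only in genes with a mean log2(FPKM + 1) above 2. In the ΔhepA comparison the fit recovered 11.2% of changes of 1 on the log2 scale, 62% of changes of 2, 84.8% of 3 and 95.6% of 4. In the ΔlaeA comparison it recovered 11.2%, 63.6%, 86.8% and 99.2%, so most smaller changes are not detectable at this replication.

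The comparisons, tests and most alternatives were fixed before the data were examined. The gene lists fixed then were patterns over descriptions, and the reference table has only symbols. Of 23 patterns, 3 matched at least 5 tested genes. So 24 lists were rewritten as symbols after the symbols, library summaries and the 20 most abundant genes had been seen, but before any test. They were tested with limma's camera at a preset correlation of 0.01 and with an estimated one. Genes were named by a fixed rule. It takes the 8 largest rises and 8 largest falls among called genes with a symbol, no overlap between groups (chance gives 10% for 3 against 3) and a higher mean of at least 5 FPKM. It adds up to 3 called members of each list and, between the deletion strains, the 4 largest in each direction. Genes of a run of neighbours, genes quoted as examples of a list without being called, and genes said to be chosen after their values were seen are named besides; all were picked with their values known. Runs of at least 4 called neighbours were compared with 1000 permutations of the calls, and the overlap of the comparisons with unchanged groups simulated against shared controls (100 draws).

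Alternatives were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM, median-ratio, quantile and TPM scaling, a fit on 2 groups, no mean trend, library weights, the replicate number as a block, and each library left out. Alternatives chosen after seeing the data left out the 3 libraries that lay apart, used the mitochondrial share as a covariate, or removed mitochondrial, rRNA and tRNA genes. The library-weight estimate did not converge and is left out of the 13 other fits. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.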

Results

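The data were poly(A)-enriched RNA-seq libraries of Aspergillus luchuensis mut. kawachii, the white koji mould used to saccharify starch for shochu. They came from a control strain and from 2 deletion strains, ΔhepA and ΔlaeA, with 3 libraries each. HepA is the Aspergillus homologue of heterochromatin protein 1, and LaeA is a nuclear regulator of secondary metabolism. Expression was given as FPKM for 12941 genes of the 8 chromosomes and the mitochondrial genome. The reference gave a gene symbol for 2243 of them, so most genes are named below by locus tag. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries. Read totals were not used here. The size of the smallest steps among low FPKM values gave depths, relative to control replicate 3, of 0.941 and 0.843 for control replicates 1 and 2. The ΔhepA replicates 1 to 3 stood at 1.03, 0.9 and 0.975, and the ΔlaeA replicates at 0.97, 0.66 and 0.518. Low genes were therefore measured least precisely in ΔlaeA replicates 2 and 3.

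The deleted genes could not be read out by name, because neither hepA nor laeA is a symbol in the reference used. Which loci were deleted was therefore not settled here, and a gene near 0 in all libraries of one deletion strain can be a deleted gene or a gene with lower expression. Libraries were not separated by strain alone, and strains are compared here as the labels give them. On the first principal component of log2(FPKM + 1), 39.1% of the variance, ΔhepA replicate 2 (28.8), ΔlaeA replicate 2 (53.6) and ΔlaeA replicate 3 (72.8) lay apart from the other 6 libraries (-46.4 to -9.8). In these 3 libraries mitochondrially encoded genes took 2.85%, 3.04% and 7% of the FPKM sum, against 1.09% to 1.67% in the other 6. On the second component, 19% of the variance, control replicate 1 had the highest value (55.9).

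**Figure D1:**
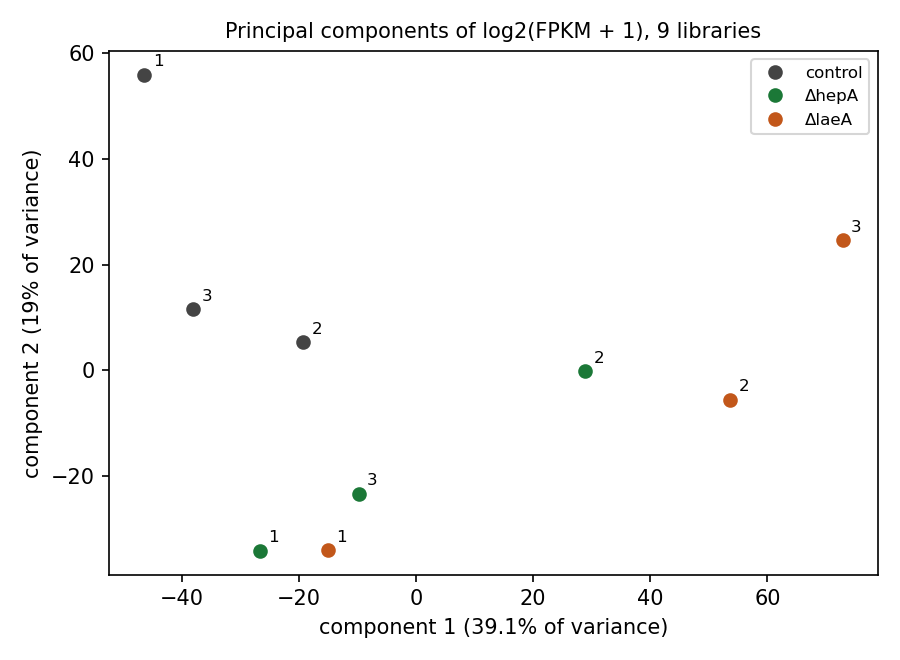
Principal components 1 and 2 of log2(FPKM + 1) over 10009 genes. Each point is 1 library, coloured by strain and marked with its replicate number. ΔhepA replicate 2 and ΔlaeA replicates 2 and 3 have positive values on component 1, and the other 6 libraries have negative ones.

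In ΔhepA against the control, 4 neighbouring genes on chromosome 4 fell, AKAW2_40841A to AKAW2_40844S (2417341 to 2424135 in the files' coordinates, which match the reference assembly). The reference gives these genes no symbol. AKAW2_40841A fell from 1246 ± 149 to 69.5 ± 21.7 FPKM (SD, n = 3; log2 difference -4.19). AKAW2_40842S fell from 281 ± 46.4 to 10.5 ± 5.16 FPKM (log2 difference -4.72). AKAW2_40843S went from 312 ± 36.4 to 44.9 ± 3.24 FPKM (log2 difference -2.76) and AKAW2_40844S from 346 ± 41.0 to 26.9 ± 5.84 FPKM (log2 difference -3.65). The limma adjusted p of the 4 genes lay between 0.000212 and 0.00132. AKAW2_80200S (chromosome 8, 589285 to 590334), chosen after its values were seen, stood at 54.6 to 69.5 FPKM in the controls and at 0.41, 0.48 and 1.31 FPKM in the ΔhepA libraries (log2 difference -5.23, limma adjusted p = 0.000212). These values do not tell lower expression from removal of the gene itself by the deletion. The 4 neighbours and AKAW2_80200S were called in each of the 6 fits that left out 1 library, and in 13 other fits.

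**Figure D2:**
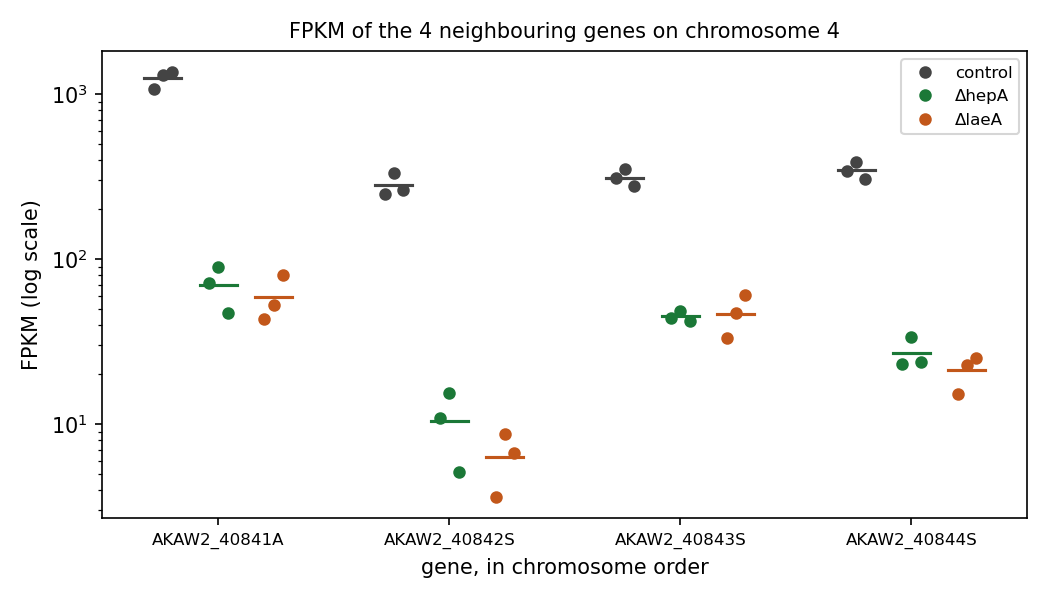
FPKM (log scale) of AKAW2_40841A, AKAW2_40842S, AKAW2_40843S and AKAW2_40844S in chromosome order. Points are single libraries, coloured by strain, and bars are means of 3. For each gene the 6 deletion libraries lie below the 3 controls.

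Among genes with a symbol, 1 rose and 3 fell in ΔhepA. nscA, the polyketide synthase gene of the neosartoricin cluster in other fungi, rose from 2.79 ± 2.32 to 42.5 ± 23.96 FPKM (SD, n = 3; log2 difference 3.50 ± 0.586 SE, limma adjusted p = 0.0372). SED2, a secreted tripeptidyl peptidase of the sedolisin family, fell from 21.2 ± 17.3 to 1.44 ± 0.285 FPKM (log2 difference -2.89, adjusted p = 0.0462). GIT1_1, named after a yeast glycerophosphoinositol permease, fell from 190 ± 99.5 to 25.7 ± 3.29 FPKM (log2 difference -2.66, adjusted p = 0.0425). coaT fell from 599 ± 273 to 113 ± 30.7 FPKM (log2 difference -2.30, adjusted p = 0.0366). These 4 calls are fragile. Without control replicate 1 the adjusted p was 0.187 for nscA, 0.173 for SED2, 0.205 for GIT1_1 and 0.17 for coaT, and without any 1 ΔhepA library it lay between 0.0538 and 0.155. Without control replicate 2 it was 0.0671 for nscA and 0.0655 for coaT, and without control replicate 3 it was 0.135 for GIT1_1.

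The genes beside nscA on chromosome 8 were higher in the ΔhepA libraries too; they were chosen after their values were seen. AKAW2_80649S (1807057 to 1808058) stood at 9.46 to 55.95 FPKM in the controls and rose to 533 ± 349 FPKM (SD, n = 3; log2 difference 4.47, limma adjusted p = 0.0485). That call was lost without any 1 library other than control replicate 3 (adjusted p 0.081 to 0.224). nscC, a monooxygenase gene, stood at 3.49 to 16.9 FPKM in the controls and 44.5 to 238 FPKM in ΔhepA (log2 difference 4.05, adjusted p = 0.11). AKAW2_80651S had a log2 difference of 3.96 (adjusted p = 0.0808; 0.0461 without control replicate 3). nscR, the regulator gene at the end of the group, had a log2 difference of 0.37 (adjusted p = 0.817). The other 3 genes that rose were all on chromosome 7, also named after their values were seen. They were AKAW2_70316A (1676 ± 510 against 505 ± 107 FPKM), AKAW2_70670S (1714 ± 92.8 against 580 ± 33.4 FPKM) and AKAW2_70985S (13.7 ± 0.725 against 3.19 ± 0.671 FPKM), each with an adjusted p of 0.0366. None of these 3 was called without control replicate 1 (adjusted p = 0.168 for each), control replicate 3 (0.12 to 0.121) or any 1 ΔhepA library (0.0712 to 0.153). AKAW2_70670S was also not called without control replicate 2 (0.0648).

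**Figure D3:**
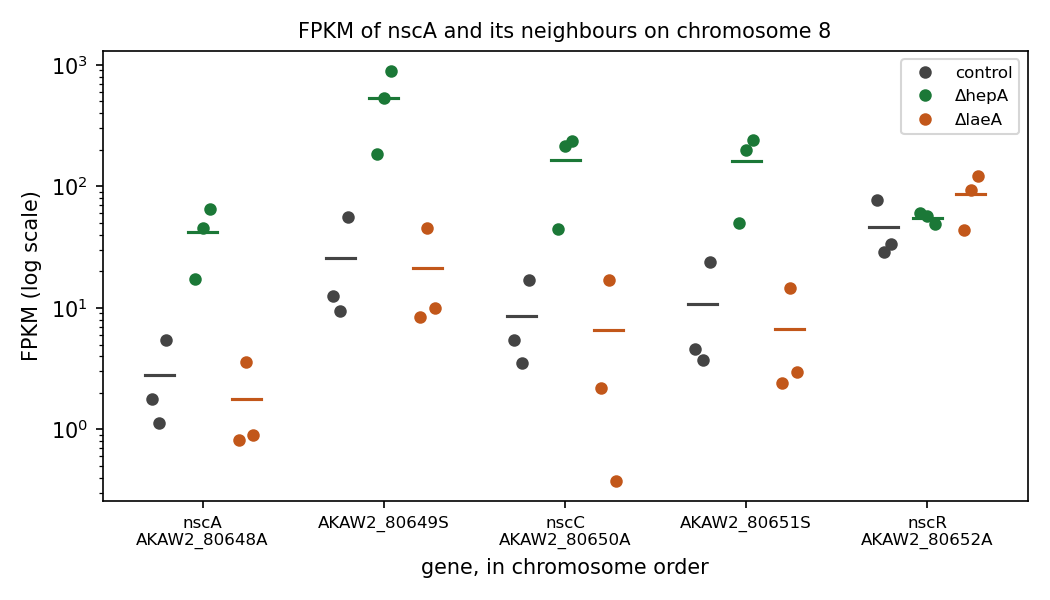
FPKM (log scale) of nscA, AKAW2_80649S, nscC, AKAW2_80651S and nscR in chromosome order. Points are single libraries, coloured by strain, and bars are means of 3. In the first 4 genes the lowest ΔhepA value, such as 17.3 FPKM for nscA, lies above the highest control value, 5.44 FPKM for nscA; in nscR the strains overlap.

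In all, 32 of 10009 tested genes changed in ΔhepA at a limma adjusted p under 0.05; 5 rose and 27 fell, each at least 2-fold. At an unadjusted p under 0.05 there were 1044. The median log2 difference of all genes was -0.15. With median-ratio scaling, which centres it, 0 genes rose and 8 fell, 7 of them among the 32. With quantile normalization 2 rose and 11 fell. The count was 7, 6, 5 and 5 without control replicate 1 and without ΔhepA replicates 1, 2 and 3, and 55 without control replicate 2. It was 7 without the 3 libraries that lay apart, an alternative chosen after seeing the data.

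Of 24 gene lists, 9 stood apart from other genes in ΔhepA by camera with a preset correlation of 0.01. None of the 9 calls held with an estimated correlation (adjusted p = 0.657 to 0.782). Each of the 55 genes of cytosolic ribosomal proteins was lower (median log2 difference -0.45, adjusted p = 5.62e-09, and 0.711 with an estimated correlation; 53 were lower with median-ratio scaling), and none passed the test alone. RPL15, for example, went from 2575 ± 215 to 1439 ± 88.7 FPKM. Genes of ribosome biogenesis were higher in 59 of 65 (median 0.27, adjusted p = 9.64e-08, and 0.711 with an estimated correlation), among them ESF2, at 78.4 ± 19.2 and 199 ± 64.9 FPKM. Chaperones were higher in 16 of 28 (median 0.33, adjusted p = 0.00142, and 0.711 with an estimated correlation), with HSP98 at 364 ± 63.7 and 1430 ± 674 FPKM. Of the 9 mitochondrially encoded genes, 9 were higher (median 0.77, adjusted p = 0.000341, and 0.657 with an estimated correlation). The mitochondrial share of the FPKM sum was 1.46%, 2.85% and 1.67% in ΔhepA replicates 1 to 3, against 1.09% to 1.32% in the controls. Genes of rRNA took 4.28%, 9.37% and 4.66%, against 3.09% to 5.54% in the controls, so replicate 2 was highest in both. Named secondary metabolite genes were higher in 15 of 23 (adjusted p = 0.0193, and 0.657 with an estimated correlation), with 1 called, nscA. Siderophore and iron genes were higher in 9 of 14 (adjusted p = 0.0263, and 0.657 with an estimated correlation). Proteases were lower in 18 of 19 (adjusted p = 0.0427, and 0.711 with an estimated correlation), with 1 called, SED2. Proteasome genes were lower in 26 of 26 (adjusted p = 0.0263, and 0.782 with an estimated correlation; 0.126 with median-ratio scaling). Nitrogen and ammonium genes were lower in 12 of 16 (adjusted p = 0.0271, and 0.711 with an estimated correlation), with AMT1 at 62.6 ± 50.4 and 4.81 ± 1.75 FPKM. Control replicate 2 weighed on AMT1: its log2 difference was -2.80 (limma adjusted p = 0.231), and -4.02 without that library (0.00415). Without the 3 libraries that lay apart, proteases, proteasome and nitrogen genes were not called (adjusted p = 0.145, 0.0782 and 0.0978). Of the lists, 3 could also be built from the patterns written before the data were examined: chromatin regulators (6 genes), asexual development (9) and ergosterol synthesis (11). In ΔhepA, as in the other comparisons, 0 of these 3 were called by camera (adjusted p = 0.589, 0.678 and 0.678 in ΔhepA) and 0 of their members changed by limma over all genes tested. At an unadjusted p under 0.05 the 3 lists had 1, 1 and 0 members in ΔhepA. Adjusted over the list alone, 0 members changed in ΔhepA. In the 24 lists the test pointed up while the median was below 0 for the tricarboxylic acid cycle, asexual development and histones, none of them called.

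In ΔlaeA against the control, the same 4 chromosome 4 genes fell. AKAW2_40841A stood at 58.6 ± 18.9 FPKM (SD, n = 3; log2 difference -4.43), AKAW2_40842S at 6.33 ± 2.58 FPKM (-5.32), AKAW2_40843S at 46.7 ± 13.4 FPKM (-2.75) and AKAW2_40844S at 21.1 ± 5.19 FPKM (-3.99). Their limma adjusted p lay between 0.000126 and 0.00168. They kept the call in each of the 6 fits that left out 1 library and in the 13 other fits.

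Several more genes fell in groups of neighbours in ΔlaeA; these groups were chosen after their values were seen. On chromosome 8, AKAW2_81087A, AKAW2_81088S, AKAW2_81090A and AKAW2_81091S (3203921 to 3213301) fell, while AKAW2_81089A between them did not pass the test (log2 difference -1.51, adjusted p = 0.0587). AKAW2_81090A went from 112 ± 76.1 to 2.21 ± 2.02 FPKM (SD, n = 3; log2 difference -5.08, limma adjusted p = 0.00168) and AKAW2_81091S from 121 ± 71.2 to 4.48 ± 2.09 FPKM (-4.39, adjusted p = 0.00168). AKAW2_81087A had a log2 difference of -2.72 and AKAW2_81088S of -2.96. On chromosome 4, AKAW2_40205S (514133 to 516110) fell from 25.7 ± 9.29 to 0.703 ± 0.685 FPKM (-3.97, adjusted p = 0.00168), and AKAW2_40206S beside it from 92.0 ± 54.9 to 5.05 ± 2.75 FPKM (-3.91, adjusted p = 0.00416). Without ΔlaeA replicate 2, AKAW2_81087A and AKAW2_81088S were not called (adjusted p = 0.108 and 0.0986). AKAW2_81087A was also not called without control replicate 1 (0.0868) or 3 (0.068).

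A group on chromosome 3 rose in ΔlaeA, again chosen after its values were seen. AKAW2_31315S rose from 1.7 ± 0.682 to 46.0 ± 40.1 FPKM (SD, n = 3; log2 difference 3.76, limma adjusted p = 0.0183). AKAW2_31317A rose from 4.99 ± 0.714 to 241 ± 215 FPKM (4.81, adjusted p = 0.0385) and AKAW2_31319S from 11.1 ± 0.944 to 148 ± 115 FPKM (3.31, adjusted p = 0.0367). FSL5 (3923091 to 3924223), named after a fusarielin cluster gene, stood at 1.9 ± 0.621 and 33.9 ± 30.3 FPKM (3.22, limma adjusted p = 0.0587, and 0.00909 without ΔlaeA replicate 1). The fit without that library called 1601 genes, so it does not single out FSL5. The values were uneven across libraries: AKAW2_31317A was at 48.0, 203 and 473 FPKM in the ΔlaeA replicates, and at 6.49, 97.8 and 65.6 FPKM in the ΔhepA replicates. All 3 called genes lost the call without ΔlaeA replicate 2 (adjusted p = 0.094, 0.172 and 0.143), without control replicate 1 (0.0801, 0.156 and 0.14) and without control replicate 3 (0.068, 0.102 and 0.0992). AKAW2_31317A and AKAW2_31319S lost it also without control replicate 2 (0.0635 and 0.059) and without ΔlaeA replicate 3 (0.0833 and 0.0684).

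Among genes with a symbol in ΔlaeA, CON10, a conidiation-specific gene first described in Neurospora, rose from 41.7 ± 10.1 to 136 ± 31.5 FPKM (SD, n = 3; log2 difference 1.68 ± 0.33 SE, limma adjusted p = 0.0385). ugd2 rose from 5.82 ± 1.08 to 17.5 ± 2.63 FPKM (1.44, adjusted p = 0.0466). Falls included SED2 (21.2 ± 17.3 to 1.80 ± 0.158 FPKM, -2.68), ACS1, an acetyl-CoA synthetase gene (103 ± 66.1 to 14.1 ± 4.08 FPKM, -2.61), and GIT1_1 (190 ± 99.5 to 28.3 ± 10.5 FPKM, -2.59). DCW1_2, named after a yeast cell wall mannosidase, fell too (log2 difference -2.56). UGA4_1, named after a yeast 4-aminobutyrate permease, fell as well (-2.26), as did SYM1_2 (-2.20). DAL2, an allantoicase gene of purine breakdown, fell from 830 ± 90.9 to 234 ± 118 FPKM (-1.93). MCCC2, a methylcrotonyl-CoA carboxylase subunit gene, fell from 31.1 ± 15.6 to 6.94 ± 1.59 FPKM (-1.93). The adjusted p of these 8 falls lay between 0.0114 and 0.0466. Without ΔlaeA replicate 2 none of the 10 genes was called (adjusted p 0.0551 to 0.214), and without control replicate 1 only DCW1_2 was (0.0518 to 0.156 for the others). Calls were also lost without control replicate 2 for CON10, ugd2 and MCCC2 (0.0632 to 0.09). The same held without control replicate 3 for CON10, ugd2, GIT1_1, UGA4_1, SYM1_2, DAL2 and MCCC2 (0.0711 to 0.103), and without ΔlaeA replicate 3 for ugd2, SED2, DAL2 and MCCC2 (0.0523 to 0.0875).

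In all, 109 of 10009 genes changed in ΔlaeA at a limma adjusted p under 0.05 (2164 at an unadjusted p under 0.05); 17 rose and 92 fell, each at least 2-fold. The median log2 difference of all genes was -0.21. Median-ratio scaling gave 42 rises and 88 falls, and quantile normalization 60 rises and 100 falls. A fit without ΔlaeA replicate 1 keeps only replicates 2 and 3 of that strain, which both lay apart, while no control did. In such a fit the gap between libraries and an effect of the deletion cannot be told apart. Leaving out ΔlaeA replicate 1 had the largest effect on the count, which was then 1601. It was 21 without ΔlaeA replicate 2, 26 without control replicate 1, 57 without control replicate 3, and 9 without the 3 libraries that lay apart, where ΔlaeA keeps 1 library. Of the 109 genes, 19 were called in each of the 6 fits that left out 1 library.

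Of the 24 gene lists, 1 was called in ΔlaeA. Genes of cytosolic ribosomal proteins were lower in 48 of 55 (median log2 difference -0.36, adjusted p = 0.0454 by camera with the preset correlation, 0.81 with an estimated correlation). With median-ratio scaling 34 of the 55 were lower and the list was not called (adjusted p = 0.109), nor was it without the 3 libraries that lay apart (0.0878). In asexual development 1 of 18 genes rose, CON10, and abaA, a regulator of conidiophore development, stood at 23.7 ± 11.5 and 5.54 ± 1.82 FPKM (limma adjusted p = 0.0587; 0.0149 without ΔlaeA replicate 1). Among nitrogen genes 1 of 16 fell, DAL2; among fermentation genes 1 of 6 fell, ACS1; and among proteases 1 of 19 fell, SED2. Chromatin and velvet regulators had 0 of 26 called. In it veA, a velvet-family partner of LaeA in Aspergillus nidulans, stood at 34.4 ± 2.77 and 11.6 ± 4.78 FPKM (limma adjusted p = 0.0668, and 0.0128 without ΔlaeA replicate 1). The fit without ΔlaeA replicate 1 called 1601 genes, so its low p does not single out abaA or veA. Of the 3 lists built from the earlier patterns, chromatin regulators and asexual development each had 1 member that fell adjusted over the list alone, and 0 over all genes tested (1, 2 and 4 members of the 3 lists at an unadjusted p under 0.05). The test pointed up while the median was below 0 for asexual development, antioxidant enzymes and mitochondrially encoded genes, none of them called, and the mean was below 0 while the median was above it for secondary metabolite genes.

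Compared directly, ΔlaeA and ΔhepA differed in 5 genes at a limma adjusted p under 0.05 (950 at an unadjusted p under 0.05). AKAW2_80200S (adjusted p = 0.00162) and AKAW2_51607S (82.2 ± 14.5 against 20.8 ± 3.49 FPKM, SD, n = 3; adjusted p = 0.0406) were higher in ΔlaeA. AKAW2_10350A, AKAW2_60103A and AKAW2_81091S were lower. AKAW2_10350A (chromosome 1, 1026412 to 1027642) stood at 0.24, 0.7 and 0 FPKM in ΔlaeA against 8.06 to 13.5 in ΔhepA and 10.42 to 21.98 in the control. AKAW2_60103A (chromosome 6, 286517 to 286759) was listed at 0 in the 3 ΔlaeA libraries and at 5.25 to 46.2 FPKM in the other 6. For AKAW2_80200S, AKAW2_10350A and AKAW2_60103A the values do not tell a change of expression from removal of the gene by the deletion. AKAW2_10350A and AKAW2_60103A lie on different chromosomes, so removal of 1 locus would account for at most 1 of them. Apart from AKAW2_80200S, each call was lost without ΔlaeA replicate 2 or 3 (adjusted p 0.0648 to 0.12). AKAW2_10350A, AKAW2_51607S and AKAW2_81091S lost it without ΔhepA replicate 2 or 3 (0.0885 to 0.213), and AKAW2_51607S and AKAW2_81091S without ΔhepA replicate 1 (0.0783). nscA did not pass this test (log2 difference -3.93, adjusted p = 0.0594). Of the 3 lists built from the earlier patterns, asexual development had 1 member lower in ΔlaeA adjusted over the list alone. Of the 24 gene lists, ribosome biogenesis was lower in ΔlaeA in 61 of 65 genes (median -0.68, adjusted p = 8.93e-10 by camera with the preset correlation, 0.965 with an estimated correlation). Without ΔlaeA replicate 1, that strain keeps only replicates 2 and 3, which lay apart, while ΔhepA replicates 1 and 3 did not. That fit raised the count of 5 to 257, so the larger count can hold the gap between libraries. The count was 1 without ΔlaeA replicate 2 or 3. It was 2 without ΔhepA replicate 2 or 3, and 0 without the 3 libraries that lay apart.

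Of the genes called by limma in the 2 deletion strains, 21 fell in both, 0 rose in both and 0 moved in opposite directions. The 21 include the 4 chromosome 4 genes, SED2, GIT1_1 and AKAW2_40206S. Unchanged groups simulated against shared controls gave 0 shared calls in 100 draws, a value that leaves out the effects of the deletions. Independent lists of these sizes would share 0.248 falls, a value that leaves out the shared controls, so the excess over either is not shown to be a shared effect. The 3 controls cannot be divided into sets of at least 2 each, so part of the excess in the number of shared falls may come from the shared controls. Across genes, which are not independent replicates, the log2 differences had Pearson r = 0.651 (0.501 simulated) and Spearman rho = 0.633 (0.464 simulated). Their covariance was 0.312 against 0.12 simulated, a difference of 0.192. The simulation drew the libraries independently of each other. In the data, deviations from group means had correlations from -0.559 to 0.424 between ΔhepA and ΔlaeA libraries. These deviations sum to 0 within each strain, so they do not show whether the strain means share such variation. Libraries that lay apart were in both deletion strains and not among the controls. The excess in r, rho and covariance is therefore not shown to be a shared effect either. The number that fell in both was 6 without control replicate 1 and 46 without control replicate 2. It was 5, 4 and 4 without ΔhepA replicates 1, 2 and 3. Without ΔlaeA replicate 1, 34 moved together (32 fell and 2 rose), and without ΔlaeA replicate 2, 5 did. With median-ratio scaling it was 6.

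Called genes were set against the gene order. The chromosome 4 genes made up the 1 run of at least 4 consecutive tested genes in each strain. In 1000 permutations of the calls there was no such run (permutation p = 0.001, the smallest they can give). The permutations take neighbouring genes as independent. Differences between 2 libraries of one strain were also correlated between a gene and the gene next but one (0.0275 to 0.107). Both strains were set against the same controls, so the runs are not independent of each other. Within 100 kb of a chromosome's outermost genes, 2 of 347 genes fell in ΔhepA against 25 of 9650 elsewhere (odds ratio 2.23, Fisher's exact test, two-sided p = 0.241). In ΔlaeA 2 of 347 fell against 90 of 9650 elsewhere (odds ratio 0.616, Fisher's exact test, p = 0.773). No direction passed after adjustment over the comparisons (adjusted p = 1).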

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

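The tests of the exchanged labels, of the scaling and of the chromosome 4 genes, and the 10 splits per comparison, were chosen or read only after the results were seen; those of depth and abundant transcripts were set before. The effects of the 2 deletions differed, by the test of the difference itself, in 5 genes. On the log2 scale, the ΔlaeA effect minus the ΔhepA effect was 4.61 for AKAW2_80200S, 1.93 for AKAW2_51607S, -3.14 for AKAW2_10350A and -3.28 for AKAW2_81091S. For AKAW2_60103A it was -4.28, a fitted value that depends on the pseudocount, since the gene is listed at 0 in ΔlaeA. AKAW2_80200S, near 0 in the 3 ΔhepA libraries, and AKAW2_10350A and AKAW2_60103A, near or at 0 in the 3 ΔlaeA libraries, were not tested for being deleted genes themselves, so these 3 are not shown to be effects of a deletion on other genes. AKAW2_80200S was called without each of the 6 libraries in turn. The other 4 were not called without ΔlaeA replicate 2 or 3: the adjusted p was 0.0648 and 0.0766 for each of AKAW2_60103A and AKAW2_10350A, 0.0883 and 0.12 for AKAW2_51607S, and 0.12 and 0.119 for AKAW2_81091S. Without ΔhepA replicate 1, AKAW2_51607S and AKAW2_81091S were not called (0.0783 for both). Without ΔhepA replicate 2 the adjusted p was 0.0885, 0.178 and 0.201 for AKAW2_10350A, AKAW2_51607S and AKAW2_81091S, and without ΔhepA replicate 3 it was 0.156, 0.213 and 0.213.

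ΔhepA replicate 2 and ΔlaeA replicates 2 and 3 lay apart from the other 6 libraries; low depth is argued against, since among genes with a mean of at least 50 FPKM the gap on the first component was still 35.6% of its range (32.4% over all genes). So is a larger share of mitochondrial and other abundant transcripts, since without mitochondrial, rRNA, tRNA and the 100 most abundant genes and with median-ratio scaling the gap was 29.96%. An exchange of labels between ΔhepA replicate 2 and ΔlaeA replicate 1 stays open, though most values go against it: genes at least 8-fold below the other 6 libraries, as a deleted gene would be, number 1 in ΔhepA (AKAW2_80200S) and 2 in ΔlaeA (AKAW2_10350A and AKAW2_60103A) as given, and 0 in the groups an exchange would give. The rule set for excluding an exchange was not met, since at 4-fold those groups hold 1 gene, against 1 and 4 as given. That gene is low in ΔhepA replicate 2 and ΔlaeA replicates 2 and 3, the libraries that lay apart, so it can also reflect their gap. The other group of an exchange holds 0 genes at 4-fold. Of the tests tried earlier, 1 read AKAW2_80200S and AKAW2_60103A alone. Another, on 3 genes chosen without both libraries, did not decide (medians 0.392 and 0.355, with AKAW2_80200S against an exchange and tfb5 for it). A difference in culture, harvest or batch stays open too, and no biological explanation was tested.

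In both strains falls outnumbered rises. For ΔlaeA, scaling between libraries as the whole cause is argued against: after median-ratio scaling 67.7% of 130 called genes fell (95% Wilson interval 59.2% to 75.1%, which treats genes as independent), against 84.4% as deposited. Part of the excess may still come from scaling. For ΔhepA 8 genes were called after it, of which 100% fell; these are too few to decide.

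The 4 chromosome 4 genes fell in both strains. A control library out of line is argued against, since the weakest log2 difference of any of the 4 genes was -2.66 without any 1 control. The lowest values in a deletion library were 43.4 FPKM for AKAW2_40841A, 33.3 for AKAW2_40843S and 15.3 for AKAW2_40844S. They argue against a loss of the whole stretch from both strains. For AKAW2_40842S the lowest was 3.6 FPKM, against a control mean of 281, which does not decide for that gene. A strain difference between the control and both deletion strains other than the named deletions may be the cause: all 6 deletion libraries lay below the controls, which both explanations require, so these cannot be told apart.

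Each comparison of 3 against 3 libraries allows 10 splits, too few for a share under 0.05. For ΔhepA 1 split gave as many as the real 32 genes, the real one, and the highest other gave 1; for ΔlaeA 1 split gave as many as 109 and the highest other gave 1. Between the deletion strains 2 splits gave at least the real 5 genes. The highest other gave 1798, with ΔhepA replicates 1 and 3 and ΔlaeA replicate 1 on one side. That split parts the 3 libraries that lay apart from the other 3, so its count restates their gap, a structure of the samples other than strain, and says nothing of its cause. For gene lists, ΔhepA had 9 and the highest other split 7 (1 split as large). ΔlaeA had 1 and the highest other 9, and the comparison of the deletion strains had 1 and the highest other 8; in both, all 10 splits gave at least as many.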

How the results depend on the processing

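Alternatives without 3 libraries, with the mitochondrial share, and without mitochondrial, rRNA and tRNA genes were chosen after seeing the data. Where no cause is named, the cause was not tested. For ΔhepA (32 genes) the count was 11 with a pseudocount of 0.1, 13 without a filter, 8 with median-ratio scaling, 13 with quantile normalization, 14 fitted on 2 groups, 7 without the 3 libraries that lay apart and 87 with the mitochondrial share; leaving out 1 library gave 5 to 55. For ΔlaeA (109) it was 211 as TPM, 49 fitted on 2 groups, 9 without the 3 libraries and 46 with the mitochondrial share; leaving out 1 gave 21 to 1601. Between the deletion strains (5) it was 1 with a pseudocount of 5, 0 fitted on 2 groups, 0 without the 3 libraries and 1 with the mitochondrial share; leaving out 1 gave 1 to 257. The overlap (21) was 8 with a pseudocount of 0.1, 9 without a filter, 6 with median-ratio scaling, 8 with quantile normalization, 8 fitted on 2 groups and 5 without the 3 libraries; leaving out 1 gave 4 to 46. Library weights gave 4260, 4268 and 2794 genes and an overlap of 2089. That estimate did not converge, with weights of 9.6 and 9.56 for control replicate 3 and ΔhepA replicate 3 against 0.236 to 1.7 for the others. The settings not named in this part moved these counts by less than 1.5 times.

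Replicate numbers did not pair the libraries: same-numbered deviations had correlations from -0.22 to 0.423. With the replicate block the counts were 6, 174 and 1, the overlap 5, and the lists called 11 for ΔhepA, 0 for ΔlaeA and 1 between the strains.

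With an estimated correlation 0 lists were called in any comparison. For ΔlaeA 0 were called with median-ratio scaling and 3 without the 3 libraries, and between the strains 6 without the 3 libraries. The run of 4 genes gives 0 runs of at least 6 genes in either strain by its length. For genes that rose in ΔlaeA, the odds ratio near chromosome ends was 0 within 100 kb and 1.62 within 200 kb (Fisher's exact test, p = 0.375), on 2 genes. For AKAW2_80200S in ΔlaeA, not called, the log2 difference was -0.62, and 0.20 without the 3 libraries. Where ΔlaeA keeps 1 library, that library is assumed to vary like the other groups. The 64 results for named genes include some that were not called in the main fit. Of the called ones, most lost the call without the 3 libraries. In the fit on 2 groups, where fewer libraries set the spread, 22 lost it. Depth limits low genes in ΔlaeA replicates 2 and 3. By a separate, coarser estimate, 1 fragment of a 1 kb gene is worth about 0.366 and 0.518 FPKM there, against 0.277 in control replicate 3. For ΔlaeA replicate 2 this puts the depth nearer to control replicate 3 than the relative depth of 0.66 does, so its depth is known only roughly.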

Other observations

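The genes of the first 2 paragraphs were picked out after their values were seen, and the test of neighbouring genes was set before. The 4 genes of this paragraph did not pass the limma test and stand for no gene list. YHM2, a mitochondrial citrate carrier gene, stood at 533 ± 140 FPKM in the control, 277 ± 44.8 in ΔhepA and 235 ± 42.9 in ΔlaeA (SD, n = 3; adjusted p = 0.228 and 0.065; in ΔlaeA 0.043 without control replicate 2 and 0.0193 without ΔlaeA replicate 1). SFC1, a succinate-fumarate carrier gene, stood at 18.5 ± 9.48, 2.54 ± 1.74 and 3.21 ± 2.26 FPKM (adjusted p = 0.112 and 0.0795). facB, a regulator of acetate use, stood at 34.2 ± 11.2, 15.4 ± 2.16 and 11.3 ± 3.69 FPKM (adjusted p = 0.275 and 0.0599; in ΔlaeA 0.0127 without ΔlaeA replicate 1). AMY1, an alpha-amylase gene, stood at 1174 ± 143, 579 ± 68.0 and 510 ± 327 FPKM (limma adjusted p = 0.344 and 0.0864, and in ΔlaeA 0.00431 without ΔlaeA replicate 1). The fit without ΔlaeA replicate 1 called 1601 genes in ΔlaeA, so its low p does not single out YHM2, facB or AMY1.

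argB, an ornithine carbamoyltransferase gene often used as a selection marker in Aspergillus, stood at 359, 588 and 233 FPKM in ΔlaeA. It stood at 118 to 154 FPKM in ΔhepA and 82.1 to 143 in the control. The log2 difference of ΔlaeA was 1.63 (limma adjusted p = 0.0586, 0.0268 without ΔlaeA replicate 1 and 0.0354 without ΔlaeA replicate 3). Without ΔlaeA replicate 1, 1601 genes were called, so that fit does not single out argB. AKAW2_30784S (chromosome 3, 2351494 to 2351778), called in ΔlaeA (limma adjusted p = 0.008), was listed at 0 in the 3 controls and at 9.15, 11.5 and 14.8 FPKM in ΔlaeA. Its log2 difference was 3.66, and 3.34 without the 3 libraries that lay apart. It was not called between the deletion strains, so the rise is not shown to be particular to ΔlaeA.

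A hypothesis set before its test was that genes of one neighbourhood change together in each mutant. The correlation of a gene's log2 difference with that of the gene next but one, across genes, was 0.122 for ΔhepA and 0.101 for ΔlaeA, above each of 1000 permuted gene orders (highest 0.0336 and 0.0296). The 9 differences between 2 libraries of one strain gave 0.0275 to 0.107. ΔlaeA lay within that range, against the hypothesis as stated. ΔhepA lay above it by a narrow margin, as the hypothesis requires. Differences of single libraries carry more noise than differences of means, which can lower such correlations; this was not tested. Pairs of a library that lay apart with one that did not gave 0.0807 to 0.107, and the other pairs 0.0275 to 0.0524. The range thus followed the gap between libraries. The ΔhepA difference sets a group with ΔhepA replicate 2, which lay apart, against controls that did not. Its narrow margin can therefore come from that gap and does not decide for the hypothesis. ΔlaeA against ΔhepA gave 0.0894, within the range.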
